A study of Zea mays with 14 samples.

How the data were processed

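RNA from maize embryonic axes was hybridised to single-colour Affymetrix maize arrays, 14 in all. Per the labels, 1 g of axes was used for each total RNA sample and 2 g for each polysomal one, and 4 µg of RNA was labelled per array. The table deposited by the authors holds log2 signals, 1 value per probe set and array, and the only tool that the submitters' processing notes name is limma. The background correction, normalization and summary method were not given in the sources used here. The values of all arrays appear to have been put on a common scale before deposit, since array medians lie between 7.27 and 7.64 and upper quartiles between 9.42 and 9.52. The medians of the 0 h arrays (7.27, 7.27 and 7.36) were below those of all other arrays (7.52 to 7.64). No further normalization was applied for the main results. Of 17734 probe sets, 113 control probe sets were left out of the tests, leaving 17621. No filter on low signals was used, and no column belonged to a sample of another series.

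Groups were taken from the sample titles: total RNA at 0 h, total RNA at 24 h, total RNA with insulin, polysomal RNA without insulin and polysomal RNA with insulin. Arrays that the titles call technical replicates were averaged with the biological array of the same sample, which gave 11 biological samples. All 5 groups were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with no covariate, since the arms hold 1 to 3 samples and share 1 estimate of the spread (residual degrees of freedom 6, prior degrees of freedom 3.20). The insulin group of total RNA is a single biological sample, so its variability is assumed to equal that of the other groups. The contrasts were 24 h against 0 h, polysomal without insulin against total at 24 h, insulin against none in polysomal RNA, insulin against 24 h in total RNA, the difference between the last pair, and polysomal against total RNA with insulin. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets. Results are log2 differences with their standard errors.

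Gene names came from the platform annotation, which dates from 2007 and can be old: 1452 tested probe sets (8.24%) had exactly 1 gene, 1 had several and 16168 had none. The Entrez gene of 1377 of them was found in the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, which supplied locus names and synonyms. No coordinates are given, since the build behind the probe sets was not given in the sources used here. Each of the 1108 genes was represented by its probe set with the highest mean. Identifiers of probe sets without a gene are not printed.

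Genes were named in the text by a fixed rule. It takes genes whose name is not a placeholder, called and with groups that do not overlap: the 10 largest rises and 10 largest falls per comparison, the 3 called members with the largest change in the direction of each list that camera called, and, called or not, the 3 highest and 3 lowest cytosolic ribosomal proteins. Where nothing was called, the 3 genes with the smallest p each way are given as values. Other genes appear as examples of list members and were chosen after their values were seen. A set of 26 lists was defined by rules on gene symbols and titles: cytosolic and organellar ribosomal proteins, translation factors, ribosome biogenesis, LEA proteins and dehydrins, seed storage proteins, oil body proteins, heat shock proteins and chaperones, antioxidant enzymes, histones, cell cycle and DNA replication, tubulins and actins, cell wall growth, glycolysis and fermentation, glyoxylate cycle and lipid breakdown, mitochondrial respiration, ubiquitin and proteasome, proteases and inhibitors, photosynthesis, auxin, abscisic acid and gibberellin, TOR and PI3K signalling, aquaporins, defence and wounding, endosperm markers, and aleurone and scutellum markers. Gene titles were not used, because the tables hold symbols and synonyms only, so the lists are shorter than the rules intended. The 18 lists with at least 5 genes were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry as alternatives. The groups, tests, these lists, the naming rule and the alternatives chosen beforehand were fixed before the data were examined.

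The steps were tested on simulated data with the standard deviations and means of the real probe sets, in which 200 of 17621 probe sets were changed by 1 or 2 on the log2 scale. The share recovered at these sizes was 30% and 81% for germination, 34% and 88% for polysomal against total RNA, 62% and 96% for insulin in polysomal RNA, and 18% and 67% for insulin in total RNA, with 4 to 8 unchanged probe sets called. A shift of 0.5 in the ribosomal protein list was recovered in each of these comparisons, but the simulated probe sets were drawn independently of each other. Genes of a real list can vary together, so this recovery does not measure the power of the list tests in the real data. The simulated samples were also independent of each other, so the shares for single probe sets need not hold where real samples vary together. Alternatives chosen beforehand were quantile normalization of all arrays or within each RNA class, centring each array on its median, leaving out the probe sets with a mean signal below the median one, leaving out the technical arrays, counting them as separate replicates or as a random block (duplicateCorrelation), eBayes with trend and robust, fitting the compared groups alone, the replicate number as a block, and leaving out each biological sample. A sample was left out only for the comparisons that use its group. Added after the data were seen were array 1-R alone for total insulin RNA, the poly-A control level (for germination and insulin in polysomal RNA) or the ef1a 3 prime minus 5 prime difference (for these and polysomal against total RNA) as a covariate, and the gene lists with each sample left out. Hybridization controls, poly-A controls and 3 prime minus 5 prime differences of control probe sets were used as quality measures only. The hybridization controls (27 probe sets) had a mean log2 signal of 4.22 on the array of polysomal insulin sample 2 against 9.73 to 11.18 on the other 13 arrays, while that array's median and upper quartile lay within the range of the others; it was kept, and results without it are among the alternatives.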

Results

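Transcript levels were measured in maize (Zea mays) embryonic axes, the part of the embryo that grows into root and shoot, during germination and after exposure to insulin. The series holds 14 single-colour Affymetrix arrays from 11 biological samples in 5 groups. Total RNA came from quiescent axes at 0 h (2 samples) and from germinated axes at 24 h (2 samples, named M4 and RB in the labels). Polysomal RNA, the fraction bound to several ribosomes at once, came from axes imbibed for 22 h and then kept for 2 h in culture medium without insulin (3 samples) or with 200 µU/mL of bovine insulin (3 samples). Total RNA from insulin-treated axes was represented by 1 biological sample on 2 arrays. A pair of arrays from 1 RNA sample correlated at r = 0.993 to 0.998 across probe sets in the 3 such pairs. The 10 pairs of different biological samples of a group had 0.965 to 0.990. Pairs from different groups ranged from 0.793 to 0.997, so samples did not always lie closest to their own group. Array 1-R of the total insulin sample correlated at 0.997 with the technical array of M4, and at 0.993 with the other array of its own sample. Probe sets are not independent replicates, so these correlations describe the arrays only. Arrays have no read depth, and their number limits the precision: the median standard error of a log2 difference was 0.23 for germination, 0.21 for polysomal against total RNA, 0.19 for insulin in polysomal RNA and 0.28 for insulin in total RNA. Apart from the word biological in the labels, nothing said that the samples of a group came from separate batches of axes, so the p-values measure the spread between these samples. That spread was pooled over all groups, and most of its residual degrees of freedom came from the polysomal groups with 3 samples each. Standard errors and p-values for germination and for insulin in total RNA thus rest largely on the spread among polysomal samples.

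The first comparison asked which transcripts changed between quiescent and germinated axes. The largest rises among named genes included single genes of fermentation, defence, wall loosening and sugar uptake, and the largest falls included a pair of globulin genes and a pair of seed vacuole aquaporin genes. The largest rise among named genes was that of PDC (pdc1, LOC542376), a pyruvate decarboxylase of ethanol fermentation, from a log2 signal of 5.18 ± 0.49 (SD, n = 2) to 13.04 ± 0.23 (SD, n = 2), a 231-fold change; its other probe set rose by only 1.17 on the log2 scale, so the size of the rise depends on the probe set. GAPC (gpc3, LOC542333), a cytosolic glyceraldehyde-3-phosphate dehydrogenase, rose 97.6-fold, and the monosaccharide transporter MST1 (LOC542695) rose 130-fold. The gene named GLB1 with the synonym Hb (LOC541815), a plant hemoglobin and not a globulin, rose 188-fold, from 4.77 ± 0.05 (SD, n = 2) to 12.32 ± 1.43 (SD, n = 2). The beta-glucosidase glu1 (LOC542414) rose 140-fold, the lipoxygenase lox1 (LOC541856) 98.1-fold, the phenylpropanoid enzyme 4CL (LOC542166) 79.9-fold, chitinase (LOC542525) 75.4-fold, the beta-expansin expB8 (LOC542496) 71.2-fold and the tonoplast aquaporin TIP2-1 (LOC541894) 51.6-fold. Of the other 2 probe sets of expB8, 1 was called higher and 1 was not called. The deposited values do not say which signals lie above background, and most of these genes had a 0 h signal near 5, so the folds are ratios of deposited signals and neither their exact size nor their order is certain.

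The deepest fall among named genes was that of TIP3-1 (LOC541896), an aquaporin of protein storage vacuoles, from 13.47 ± 0.16 to 8.54 ± 1.00 (SD, n = 2 each). Its relative TIP3-2 (LOC541912) decreased by 3.44 on the log2 scale. The embryo globulins glb2 (LOC542382) and glb1 (LOC732801) had log2 changes of -4.71 ± 0.58 and -4.62 ± 1.11 (SE). The standard error of glb1 came mostly from other groups, since its SD was 0.12 at 24 h and 0.02 at 0 h (n = 2 each). The metallothionein-like gene mtl2 (LOC542475) had a change of -4.31 ± 1.04 (SE), and its signal at 24 h differed between the samples (9.74 ± 1.94, SD, n = 2). The sucrose synthase gene sus2 (LOC542091), the lysine-degrading enzyme lkrsdh1 (LOC541648), the asparagine synthetase AS (LOC542435), the homocysteine methyltransferase HMT-4 (LOC541876) and per-1 (LOC100037830) changed by between -3.42 and -3.07; the other probe set of AS was called at only -0.58, and that of mtl2 at -2.34. In limma's moderated test 8270 of 17621 probe sets (46.9%) passed an adjusted p of 0.05, with 3730 higher and 4540 lower at 24 h, and 2849 of the higher and 2689 of the lower ones changed at least 2-fold. Of the 1108 genes in the annotation, 332 rose and 223 fell. The adjusted p was 3.93e-07 for PDC and GAPC, 2.09e-05 for TIP3-1 and 0.00787 for glb1. Some control measures also separated the groups. The 3 prime minus 5 prime difference of control probe sets can show RNA degradation; that of ef1a was 1.46 ± 0.15 at 0 h and 0.83 ± 0.02 at 24 h, but that of actin went the other way (1.34 ± 0.33 and 2.14 ± 0.19), and those of gapdh (1.05 and 0.90) and ubiquitin (0.58 and 0.57) differed little, so the controls do not show jointly that either group was more degraded. The level of the poly-A controls, spiked-in RNAs, was 9.91 ± 0.15 and 7.78 ± 0.00 (SD, n = 2 each). With the ef1a difference as a covariate, chosen after the data were seen like that of the poly-A level, 7776 probe sets passed. The ribosomal protein gene rpl30 then lost its call (adjusted p 0.0630) at a value of 0.46 that had not shrunk. With the poly-A level 6360 passed. The values of glb1, mtl2 and per-1 then shrank to -2.92, -2.71 and -1.94 and were not called (adjusted p 0.0531, 0.0526 and 0.0937). The genes rpl30 and RPL19, also a ribosomal protein gene, lost their calls at values that had not shrunk (0.52 and -0.84, adjusted p 0.0734 and 0.0800). Within groups the poly-A level varied mostly among polysomal samples (SD 1.19 without and 1.76 with insulin), and so did the ef1a difference (0.85 and 0.62). The slopes of both covariates thus come mostly from polysomal RNA. These fits cannot show whether either measure accounts for changes between 0 h and 24 h.

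Among the gene lists fixed beforehand, that of tubulins and actins stood apart most clearly. By symbol it held tubulins and profilins but no actin gene. Of its 16 members 13 rose, none fell and 3 profilins were not called, with the same 13 when adjusted over the list alone. The tubulins tub4 (LOC542417) and tua5 (LOC542248) rose by 5.05 ± 0.29 and 5.00 ± 0.15 (SE) and tua6 (LOC542582) by 2.87 ± 0.19, while DBB11, a profilin, rose by 0.46. The camera test of the list against other genes gave an adjusted p of 0.000454, and adjusted p = 0.420 with an estimated correlation. Of 9 defence and wounding genes, 8 rose and 1 was not called (also 8 when adjusted over the list alone), with a median change of 4.59. Examples are PAL1 (LOC542258), the entry enzyme of phenylpropanoid synthesis, at 5.05 ± 0.34, and the benzoxazinoid genes bx6 at 4.87 and bx1 at 4.59; camera gave an adjusted p of 0.00528, and adjusted p = 0.455 with an estimated correlation. In cell wall growth 11 of 22 genes rose and 1, the cellulose synthase gene CesA-3, fell by 1.47 (adjusted over the list alone, 11 rose and 2 fell). The expansins expa1 (LOC541904) and expB7 (LOC542649) rose by 4.99 ± 0.50 and 4.36 ± 0.28 (SE), and the cellulose synthase CesA-2 rose by 4.22. The camera adjusted p for cell wall growth was 0.0169, but 0.120 without sample M4, and adjusted p = 0.487 with an estimated correlation.

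In glycolysis and fermentation 11 of 18 genes rose and 2 fell (adjusted over the list alone, 11 and 3). Beside PDC and GAPC, gpc4 (LOC100037774) rose by 4.27 ± 0.15 (SE), the alcohol dehydrogenase adh2 by 4.26 and the enolase eno1 by 2.14, whereas pfk1 fell by 1.96. The camera adjusted p was 0.0184, and adjusted p = 0.455 with an estimated correlation. Endosperm markers were lower as a list, with 7 of 23 fallen, 2 risen and 14 not called (adjusted over the list alone, 6 fallen and 2 risen). The list median was low in all 4 samples, at 4.89 and 4.58 at 0 h, 4.36 in M4 and 4.30 in RB. Which of these signals lie above background was not given, so the fall of the list is uncertain. The ADP-glucose pyrophosphorylase subunits sh2 (LOC542761) and bt2 (LOC541902) fell 2.95-fold and 2.83-fold, and the starch debranching enzyme zpu1 (LOC541711) fell 2.15-fold, while the sucrose synthase SH-1 rose by 2.55 and the zein gene gz27 by 0.74. The other probe set of sh2, at -0.30, was not called. At 0 h sh2 had a log2 signal of 6.56 ± 0.01 (SD, n = 2), and the zein gene z1C2, a major endosperm product, one of 3.17. The camera adjusted p was 0.0223, with a loss of the call without 0 h sample 1 (0.0722) or without sample RB (0.0898), and adjusted p = 0.455 with an estimated correlation. No list held its call with an estimated correlation in any comparison.

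The lists that camera did not call also held genes with large changes. Of 40 antioxidant enzymes 19 rose and 7 fell (21 and 7 adjusted over the list alone; camera adjusted p 0.117), with the glutathione transferase gst2 at 5.38 ± 0.18 (SE), the superoxide dismutase sod3 at -0.89 and the catalase cat1 at -0.90. In cell cycle and DNA replication 5 of 12 genes rose and none fell, over all probe sets and adjusted over the list alone: the replication clamp genes magi81248 (pcna2) and PCNA at 4.88 and 3.76, the helicase subunits MCM7 and MCM6 at 3.31 and 2.45, and cyclotide (5.15), which the list rule took in by its name and which is not a cell cycle gene. The list's camera adjusted p was 0.0853. Aquaporins went both ways, with 8 of 23 risen and 5 fallen (the same counts adjusted over the list alone; camera adjusted p 0.944), PIP2-6 at 5.28 and tip1 at -1.22 among them. Seed storage proteins had 3 fallen, 1 risen (the hemoglobin named above) and 1 not called (3 and 1 adjusted over the list alone; camera adjusted p 0.391), and the third fallen member was leg1 at -0.53. Proteases and their inhibitors had 2 risen and 4 fallen of 7 (2 and 4 adjusted over the list alone; 0.391), with the Bowman-Birk inhibitor wip1 at 5.32 and the vacuolar processing enzymes see2a and see2b at -2.59 and -2.03. Mitochondrial respiration had 2 risen and 1 fallen of 7 (4 and 1 adjusted over the list alone; 0.448), both extremes being alternative oxidases, aox3 at 5.60 and aox1 at -1.04.

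Translation factors had 2 fallen and 5 not called of 7 (also 2 adjusted over the list alone; camera adjusted p 0.177), the fallen ones being eif3 at -1.03 and eIF-5 at -1.33. None of 7 heat shock proteins and chaperones was called, also when adjusted over the list alone (camera adjusted p 0.448, median -0.63). Photosynthesis had 1 risen, C4ppdkZm1 at 4.68, and 1 fallen, me2 at -1.06, of 13 (camera adjusted p 0.391). Auxin had 2 risen and 1 fallen of 7 (0.791), namely the auxin carrier gene aic1 at 4.41, abp4 at 0.73 and abp1 at -1.11, and 3 further members (ABP1, ABP2, ABP3) were actin-depolymerizing factors taken in by their symbols. Abscisic acid and gibberellin had 1 risen, the gibberellin synthesis gene an1 at 2.00, and 1 fallen, the seed regulator vp1 at -1.02, of 5 (0.872). Of 6 aleurone and scutellum markers, 1 rose, the beta-amylase gene Amy2 at 2.81 (0.857). Counts adjusted over the list alone were the same in these 4 lists. Lists under 5 genes were not tested as lists. Of 4 LEA proteins and dehydrins, which protect dry seeds, dhn1, MGL3 and EMB5 fell, with values of -2.63, -2.16 and -1.81, and dehydrin3 rose by 3.18. Among 4 histones his2b5, H1 and his1a rose by 4.45, 3.81 and 1.78 and hon101 fell by 0.71. The oleosin ole1 had a value of -1.64 ± 0.61 (SE, adjusted p 0.0515), the isocitrate lyase ICL 1.21 ± 0.45 (adjusted p 0.0518), ubc7 -0.22 and S6K -0.11, while the growth-control kinase TOR fell by 0.71 (adjusted p 0.0379). No gene symbol matched the rules for organellar ribosomal proteins or for ribosome biogenesis, which missed at least lem1, a plastid ribosomal protein gene.

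The listed cytosolic ribosomal protein genes, from the family named in the title of the series, did not move as a group between 0 h and 24 h. Of 14 genes 2 rose, 2 fell and 10 were not called (1 and 1 adjusted over the list alone), the list median was 0.01, and camera gave an adjusted p of 0.766. RPS21 (LOC542449) rose by 1.48 ± 0.25 and rpl30 (LOC541668) by 0.45 ± 0.16 (SE), arpp2b (LOC542340), an acidic stalk protein, fell by 0.97 and RPL19 (LOC542284) fell by 0.79. The values of arpp1a (LOC542719), at 0.31, and L29 (LOC541790), at -0.51, did not pass. The median over all probe sets was -0.17, 0.01 being the list's value on that scale; with each array centred on its median, the median over all probe sets was -0.45, that of the list -0.26, and rpl30 at 0.17 no longer passed (adjusted p 0.396). That centring also moved the split of calls to 3040 higher and 7473 lower, so that 28.9% were higher against 45.1% as deposited. The call of RPL19 was lost without any 1 of the 4 samples (adjusted p 0.0625 to 0.125), and that of rpl30 without 0 h sample 2 (0.215), M4 (0.0532) or RB (0.141).

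**Figure D1:**
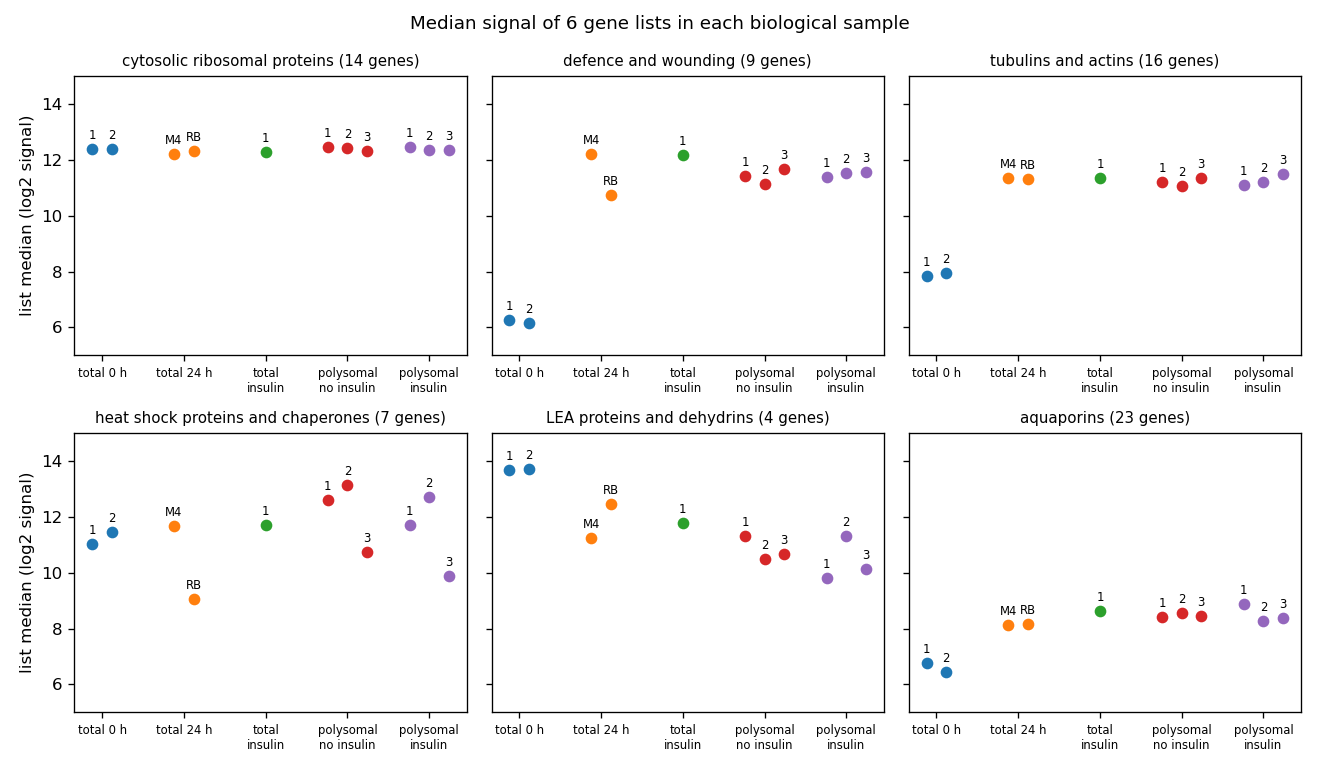
Median log2 signal of 6 gene lists (y axis) in each of the 11 biological samples, grouped on the x axis by RNA class and treatment and marked by replicate. The ribosomal protein list lay between 12.20 and 12.45 in all samples, while the heat shock list ranged from 9.04 in the 24 h sample RB to 13.15 in polysomal sample 2 without insulin.

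The 24 h samples differed from each other in several of these groups. Between RB and M4, 2014 probe sets differed at least 2-fold, 935 higher and 1079 lower in RB, against 336 between the 0 h samples. The median of RB minus M4 was -2.33 for heat shock proteins (6 of 7 lower in RB), -1.06 for defence and wounding (8 of 9 lower), -0.79 for aquaporins (18 of 23 lower), -0.61 for cell wall growth (19 of 22 lower) and 0.96 for LEA proteins (3 of 4 higher). All 14 ribosomal protein genes were higher in RB, by a median of 0.11. The spread at 24 h of GLB1, lox1, chitinase and mtl2 (SD 1.43, 1.52, 1.56 and 1.94) is the difference between these samples. Germination was refitted without each 0 h or 24 h sample in turn, which left 1 sample in that group, its spread taken from the other groups. The call of mtl2 was lost without M4 (adjusted p 0.0502), that of per-1 without either 0 h sample or M4 (0.0542 to 0.0807), and that of zpu1 without 0 h sample 2 (0.109) or RB (0.0688).

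The second comparison set polysomal RNA without insulin against total RNA at 24 h, to ask which transcripts were over- or under-represented on polysomes. Most of the named transcripts that differed were lower in polysomal RNA. AGA1 (LOC606463), an alkaline alpha-galactosidase, fell by 1.69 ± 0.24 (SE), from 11.26 ± 0.18 (SD, n = 2) to 9.57 ± 0.27 (SD, n = 3). The drought-response transcription factor dbf1 (LOC542569) fell by 1.53 and DIP1 (LOC732783), named for its interaction with DBF1, by 1.37. The chaperone gene hsp70-5 (LOC542423) fell by 1.48 ± 0.19, and its other 2 probe sets were called the same way; it lies outside the heat shock list because its symbol has a suffix. Also lower were cks (LOC542667, -1.28), GRF12 (LOC100125642, -1.08) and the endosperm marker sh2 (-0.83), at low signals of 5.01 and 4.17; its other probe set, at 0.05, was not called. Higher in polysomal RNA were HP3 (LOC542596, 1.49 ± 0.20), a histidine phosphotransfer protein, the glutathione transferase gst9 (LOC542629, 1.33) and lem1 (LOC732840, 0.95). In limma's test 190 of 17621 probe sets passed, 54 higher and 136 lower, of which 36 and 116 by at least 2-fold, and only 13 of the 190 were tied to a gene. The adjusted p was 0.0179 for HP3, hsp70-5 and dbf1, and 0.0430 for gst9.

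Of the 136 lower probe sets 32 (23.5%) had an identifier starting with ZmAffx, against 12.4% of all tested probe sets (odds ratio 2.20, 2-sided Fisher's exact test, p = 0.000322), while 1 of the 54 higher ones did (p = 0.0118 in the same exact test). The ZmAffx prefix was compared after the values had been seen. The unnamed falls with the smallest p, both with that prefix, had values of -3.94 and -3.08, and the unnamed rises with the smallest p had 1.49 and 1.41. Aquaporins were higher as a list in polysomal RNA (median 0.35, 21 of 23 higher, camera adjusted p 0.0424, adjusted p = 0.891 with an estimated correlation). None of them was called over all probe sets, and 2 rose when adjusted over the list alone; pip2b had the value 1.37 and PIP2-1 0.59. The list lost its call without RB (adjusted p 0.666, median 0.16) or without polysomal sample 2 (0.135). None of the 14 ribosomal protein genes was called (also none adjusted over the list alone), the median was 0.15 and camera gave an adjusted p of 0.826; L29 had the highest value, 0.50, arpp1a and arpp2b had 0.23 and 0.21, and RPL19 (-0.89), RPS10 (LOC541869, -0.25) and arpp3 (LOC542339, -0.17) the lowest. Heat shock genes had a median of 1.43 without a call (adjusted p 0.369), a value that leans on RB (9.04, against 11.68 in M4); without polysomal sample 3 the list was called (adjusted p 0.0135, median 2.14).

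The count of calls between polysomal and total RNA rested on single samples: it was 2301 without M4, 61 without RB, and 17, 29 and 6 without polysomal sample 1, 2 or 3. With the groups of this comparison fitted alone, 8 probe sets passed and no named gene did. The ef1a 3 prime minus 5 prime difference was 1.52, 2.73 and 1.08 in the polysomal samples without insulin. In the 24 h total samples it was 0.82 and 0.85. The means of gapdh (1.19 and 0.90), ubiquitin (0.83 and 0.57) and cyclophilin (0.04 and -0.22) were also higher in polysomal RNA. Those of gapdh and ubiquitin leaned on polysomal sample 2 (1.77 and 1.33). That of actin was not higher (means 1.93 and 2.14). The poly-A control level was 11.16, 9.83 and 8.78 against 7.78 and 7.79, and was not used as a covariate here. With the ef1a difference as a covariate, chosen after the data were seen, 10 probe sets passed and none of these named genes. RNA class was also tied to the extraction and to the 2 h in medium, in which the 24 h axes were not said to have been.

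The third comparison asked whether insulin changed which transcripts were on polysomes, for which the title of the series points to ribosomal protein mRNAs. No named gene was called. Ribosomal protein transcripts lay close to 0 in all 14 genes, from -0.15 ± 0.20 (SE) for RPS21 to 0.05 ± 0.21 for RPL19, with a median of -0.04 (camera adjusted p 0.488; none called over all probe sets or adjusted over the list alone). Between them lay arpp2b and ec2e (rpl39, LOC542444) at 0.04, RPL27A at -0.06 and rpl30 at -0.14, all with 3 samples on each side. The 14 genes are those matched by symbol among the 8.24% of tested probe sets with exactly 1 gene. The list need not hold the whole family. The same mass of RNA was labelled for each array, and the values appear to be on a common scale (medians of 7.52 to 7.58 on the polysomal arrays). A shift of most mRNAs onto polysomes would thus not show here, nor would a family moving with them. The list median was 12.20 to 12.45 across the samples, and whether changes are compressed at such signals was not tested. The genes with the smallest p among those higher with insulin were opr3 (LOC732731, 0.54 ± 0.28), the TOR kinase (LOC542211, 0.44 ± 0.20) and gs (LOC542055, 0.30 ± 0.15), and among those lower gst37 (LOC541846, -0.29 ± 0.16), C5 (LOC542462, -0.21 ± 0.13) and MFS14 (LOC542404, -0.18 ± 0.11, SE throughout). The adjusted p was 1.00 for each of them. In limma's test 0 of 17621 probe sets passed, and 57 had an unadjusted p under 0.05, fewer than the 5% of probe sets that chance gives between independent samples. The lack of calls does not show that insulin had no effect. In simulated data of this design the same test recovered 62% of probe sets changed by 1 on the log2 scale and 96% of those changed by 2. The simulated samples were drawn independently, whereas some of the real polysomal samples vary together, as described below. These shares are therefore not the power of the test in the real data.

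Heat shock proteins and chaperones were lower with insulin as a list (camera adjusted p 0.000145, adjusted p = 0.892 with an estimated correlation). All 7 genes had lower values, from -1.03 for hsp18 to -0.26 for hsfb with a median of -0.66, yet none was called, over all probe sets or adjusted over the list alone. The list median was 12.60, 13.15 and 10.76 in the samples without insulin and 11.69, 12.72 and 9.89 in those with insulin, a range within each group several times the difference between them. The ef1a 3 prime minus 5 prime difference was 1.52, 2.73 and 1.08 in the former and 2.43, 1.64 and 1.19 in the latter, and the level of the poly-A controls was 11.16, 9.83 and 8.78 and then 9.82, 11.10 and 7.62. The call was lost without sample 1 (adjusted p 0.0664) or 2 (0.382) of the untreated group, and without sample 3 of the insulin group (0.915, median -0.15).

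**Figure D2:**
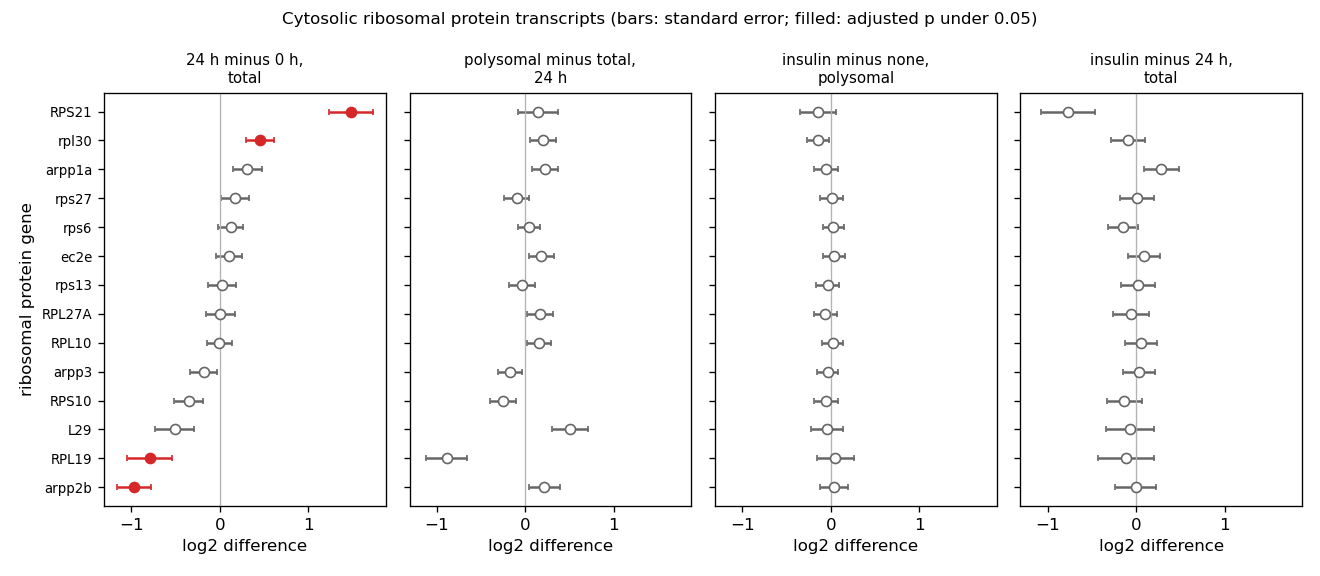
Log2 difference with its standard error (x axis) for the 14 cytosolic ribosomal protein genes (y axis) in 4 comparisons, filled where the adjusted p is under 0.05. Only RPS21, rpl30, RPL19 and arpp2b are filled, all between 0 h and 24 h, and the insulin difference in polysomal RNA spans -0.15 to 0.05.

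The fourth comparison set total RNA of insulin-treated axes (1 biological sample) against total RNA at 24 h. By the smallest p each way, the genes with higher values were the aquaporin pip2b (LOC542644, 1.28 ± 0.39), the expansin expA4 (LOC541906, 0.76 ± 0.28) and lem1 (0.59 ± 0.19), and those with lower values the cytokinin response regulator crr1 (LOC541613, -1.28 ± 0.43), the transcription factor obf3.2 (LOC542407, -1.02 ± 0.40) and the methylthioribose kinase MTK-1 (LOC542181, -0.68 ± 0.25, SE throughout). None passed (adjusted p 0.977 for each): limma called 0 probe sets, with 427 at an unadjusted p under 0.05. The lone insulin sample was assumed to vary like the other groups. Its arrays 1 and 1-R differed in the 3 prime minus 5 prime difference of actin (0.73 and 2.02), ubiquitin (-0.09 and 0.62) and gapdh (0.42 and 0.86). Those of ef1a (0.63 and 0.47) and cyclophilin (-0.36 and -0.35) differed less. Ribosomal protein genes ranged from -0.77 for RPS21 to 0.28 for arpp1a with a median of -0.03 (camera adjusted p 0.0908); RPS10 and rps6 (LOC542529) stood at -0.14 and -0.15, and ec2e and RPL10 (LOC542298) at 0.09 and 0.05. Aquaporins (21 of 23 higher, median 0.45, camera adjusted p 0.0257) and cell wall growth genes (19 of 22 higher, median 0.42, 0.0369) were higher as lists, with adjusted p = 0.523 for each with an estimated correlation and no member called, over all probe sets or adjusted over the list alone.

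Both lists lost their call without RB, aquaporins at a median of 0.09 (adjusted p 0.635) and cell wall growth at 0.13 (0.984). Without M4, 415 probe sets passed. The insulin sample and M4 differed at least 2-fold in 68 probe sets, the insulin sample and RB in 1923. The 24 h axes were not said to have been in medium, so insulin and medium cannot be told apart here.

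A test of whether the insulin difference itself differed between polysomal and total RNA called 0 probe sets in limma, with 304 at an unadjusted p under 0.05. Its total RNA part holds insulin and the 2 h in medium together, also where the difference between the insulin effects is named below. It is thus not a test of insulin alone. No list passed. Heat shock proteins had a median of -2.03 (camera adjusted p 0.0721), aquaporins -0.33 (0.0721) and ribosomal proteins 0.00126 (0.258). The values of heat shock proteins and aquaporins lean on the 24 h sample RB, with medians of RB minus M4 of -2.33 and -0.79. The insulin differences in polysomal and total RNA were uncorrelated across the 17621 probe sets, which are not independent replicates (r = -0.03, rho = 0.04). Between polysomal and total RNA of insulin-treated axes 1 probe set passed, at -3.79 ± 0.30 (SE, adjusted p 0.00813); it has the ZmAffx prefix and no gene name, and had the value -3.94 in the comparison without insulin (adjusted p 0.000362), and 1688 probe sets had an unadjusted p under 0.05. That call was lost without polysomal insulin sample 2. Ribosomal proteins had a median of 0.13 in this comparison (camera adjusted p 0.7496), and none was called.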

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

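The tests with array 1-R alone, with a quality covariate and of the gene lists with a sample left out were chosen after the results were seen. For germination, leaving out the probe sets with low mean signals gave 5254 calls and turned their balance, with 2953 higher and 2301 lower against 3730 and 4540; the median over all probe sets was then 0.05, and -0.09 with quantile normalization. The ribosomal protein median for germination was -0.26 with each array centred on its median and -0.0288 with all arrays as separate replicates; in insulin total RNA it was 0.00190 with separate arrays and 0.0122 with array 1-R alone, against 0.01 and -0.03 in the fit of the averaged arrays, so the sign of these small medians is not settled. For polysomal against total RNA the count of 190 became 314 with quantile normalization within each RNA class, 575 with the sample as a random block (correlation 0.69), 1526 with separate arrays, which treats technical arrays as samples, 8 with the groups fitted alone, which have fewer samples, and 10 with the ef1a covariate. With insulin, the count of 1 became 2 with low mean signals left out and with trend and robust, 7 with the random block, 399 with separate arrays and 0 with the groups alone. Camera with an estimated correlation called 0 lists in germination, polysomal against total, insulin polysomal and insulin total, where the preset correlation called 5, 1, 1 and 2, and fry, which does not compare a list with other genes, called 11, 0, 0 and 0; with all probe sets of each gene the counts were 6, 1, 1 and 3.

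With 1 sample left out at a time, counts ranged from 6445 to 7840 for germination, 6 to 2301 for polysomal against total RNA, 0 to 415 for insulin in total RNA, 0 to 86 for the difference between the insulin effects, 0 to 2 for polysomal against total RNA with insulin, and stayed at 0 for insulin in polysomal RNA. Removing M4 gave the highest counts 2301, 415 and 86, and removing polysomal sample 3 without insulin gave 6. The ribosomal protein median ranged from -0.0648 to 0.12 for germination, 6.65e-05 to 0.24 for polysomal against total RNA, -0.04 to -0.01 for insulin in polysomal RNA and -0.0893 to 0.0336 for insulin in total RNA. Called lists numbered 4 to 5, 0 to 2, 0 to 3 and 1 to 3 in these comparisons; without RB the only list called for insulin in total RNA was mitochondrial respiration, which was lower (adjusted p 0.0304), in place of the higher lists. Of 505 alternative values for the 34 called germination genes, 482 kept the call and 23 lost it; for the 10 called genes of polysomal against total RNA, 90 of 147 did and 57 did not, and no named gene was called in the opposite direction. Beyond the settings whose construction is given, the cause was not tested.

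Replicate numbers 1 to 3 are shared by the polysomal groups, but deviations from the group means correlated at -0.62, -0.44 and 0.60 within a number across genes. Numbers 1 and 2 thus share only a name, while number 3 correlated best with its own. Sample 1 without insulin correlated at 0.76 with insulin sample 2, and sample 2 at 0.70 with insulin sample 1. The levels of the poly-A controls in these pairs differed by only 0.06 and 0.01. These values are a hint from the data that samples were handled together, which the labels do not say, so no crossed pairing was used for a result, and the low count of 57 for unpaired samples is no sign that insulin had no effect. With the replicate number as a block in the polysomal samples alone, 0 probe sets passed (199 at an unadjusted p under 0.05). No alternative with another pseudocount was run, since the values were deposited on the log2 scale. Signal over background was not given, so changes of genes near the lowest signals are the least certain.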

Other observations

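The tests of mixed-in quiescent RNA, of less advanced germination, of the poly-A level and of 3 prime bias, and the splits for the count of probe sets, were chosen after the results were seen, while the tests of the hybridization level and of the 2 h in medium, and the splits for heat shock and for the lists, were not.

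LEA proteins and dehydrins, which are too few for a list test, went both ways in germination, with 3 of 4 fallen and 1 risen. Their median was lower at 24 h than at 0 h: 13.69 and 13.71 in the 0 h samples, 11.24 in M4, 12.44 in RB and 11.77 in total RNA with insulin, and 9.82 to 11.32 in the 6 polysomal samples. The oleosin ole1 and the isocitrate lyase ICL, which act in oil storage and use and were not called between 0 h and 24 h, were 1.29 and 1.44 higher in RB than in M4, and all 4 histone genes were lower in RB, with a median of -0.68.

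The 24 h sample RB stood apart from M4 in 2014 probe sets. The array's hybridization level does not account for this: the arrays of the total insulin sample differ in these controls by 0.954, close to the 1.02 between RB and M4, yet their difference had a slope of -0.0371 on RB minus M4 over these probe sets. An admixture of quiescent RNA as the only difference is argued against. In 35.2% of these probe sets RB lay more than 0.5 outside the interval between M4 and 0 h. An admixture beside other differences is not excluded by this. Another candidate explanation is that RB was less far advanced in germination. Of the 1063 that also changed between 0 h and 24 h, 79.1% had RB on the 0 h side (82.8% with the insulin sample in place of M4). An admixture would put RB on that side too, so these shares cannot tell it from a delay. Other values follow neither explanation. The heat shock list was at 9.04 in RB against 11.68 in M4 and 11.03 and 11.47 at 0 h. The tubulins and actins list, which rose most clearly, was 0.09 higher in RB (9 of 16) and cell cycle genes 0.03 (6 of 12). A delay or an admixture would thus cover part of the difference at most, and the rest stays open.

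The lower heat shock list with insulin in polysomal RNA may rest on differences between single samples. With the level of the poly-A controls as a covariate the heat shock median kept 0.639 of its size, a share that leaves that level open. The 10 splits of the 6 samples are too few for a share under 0.05: the real heat shock median was 0.66 in size, the highest other 1.62 and 4 of the 10 as large; the real number of lists was 1, the highest other 2 and 7 of the 10 had as many. For probe sets the real split and the highest other both called 0, so that 10 of the 10 had as many by construction, which tests nothing. At an unadjusted p under 0.05 the real split had 57 probe sets and the others 18 to 2103, which points to a structure among the 6 samples other than the insulin treatment, and an effect of insulin stays open.

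The transcripts that differed between polysomal and total RNA could come from RNA class, RNA quality, the time in medium or what lay behind the poly-A control level. That level was 8.78 to 11.16 in the polysomal samples without insulin against 7.78 and 7.79 in the 24 h total samples. No fit used it as a covariate for this comparison, so it stays open. The ef1a 3 prime minus 5 prime difference, 1 of several controls of degradation, was used as a covariate. The 190 probe sets then kept a median of 0.929 of their change (quartiles 0.838 and 1.02, median size 1.35 before and 1.24 after). In that fit 10 probe sets were called, 9 of them among the 190, and the median standard error of the 190 was 0.239 against 0.219. The share kept cannot decide on degradation. The 190 were called against the spread within groups, and the slope on ef1a comes from that same spread, mostly among polysomal samples. Probe sets that follow ef1a were thus less likely to be among the 190, and degradation stays open. The 2 h in medium as the whole cause is argued against. Between polysomal and total RNA of insulin-treated axes, both from medium, the same probe sets kept a median of 0.663 (quartiles 0.476 and 0.851). The sign was the same in 188 of 190 (98.9%). The extraction of polysomes, which comes with the RNA class, stays open and cannot be tested in this design. Presence on polysomes remains a hypothesis for these transcripts.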
